A study of Caenorhabditis elegans with 12 samples.

How the data were processed

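The series holds 12 Affymetrix C. elegans Genome Arrays of whole worms of strain N2, with 3 arrays in each of 4 groups (fed or fasted hermaphrodites, fed or fasted males). Per the labels' protocols, worms were grown at 20 C, the sexes were separated by filtration as young adults, and FUdR at 200 ug/ml was given from then on. At day 2 of adulthood they were fed ad libitum or fasted for 48 h. RNA was extracted with Trizol and RNeasy, and 250 ng was labelled with the 3' IVT Express kit with 16 h of in vitro transcription. The labels name the samples biological replicates from 3 independent experiments, so the p-values measure the spread between separate biological samples.

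The deposited values are log2 signals of MAS5, per the submitters' processing notes, which give no version. The 2% trimmed mean of the signal, taken back from log2, was 499.8 to 499.9 on all 12 arrays. Of the values, 1171 were exactly 0. Detection calls and background values were not used here. The values were used as they were, with no further normalization.

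Of 22625 probe sets, 77 control probe sets were left out. A probe set was tested where its value lay above the 40th percentile of all values (log2 6.01) on at least 3 of the 12 arrays, which left 15913. Gene names came from the array's annotation table. Of all probe sets 20766 had 1 gene, 887 several and 895 none, and 65 had a gene ID absent from the gene table of assembly WBcel235, which was used for names only. No coordinates are given. The probe sets with 1 gene stood for 17118 genes, of which 2981 had more than 1 probe set. Counts of calls are over probe sets. A named gene or a list member is represented by its probe set with the highest mean, and of 69 other probe sets of named genes 8 had the opposite sign in at least 1 comparison (11 of 145 values).

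Group means of all 4 groups were fitted across the 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend). The residual and prior degrees of freedom came to 12.2. Contrasts were fasting in hermaphrodites, fasting in males, the difference of these (interaction), and the sex difference in fed and in fasted worms. All tests are two-sided. P-values were adjusted by Benjamini and Hochberg within each contrast, and adjusted p under 0.05 was called. The overlap of the fasting responses was counted against the number that independent lists of the same sizes would share. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared the tables and figures.

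Gene lists were tested with camera at a preset inter-gene correlation of 0.01, with 1 probe set per gene and 12207 genes, for lists with at least 4 measured members, and p was adjusted over the 35 lists of each contrast. There were 26 process lists and 9 marker lists. Camera was repeated with the correlation estimated from the data, and the self-contained test fry was run beside it. Members were counted by the adjusted p over all probe sets and, separately, when adjusted over the list alone. The comparisons, the tests, the lists, the filter, the alternatives and the rule for named genes were chosen before the data were examined, except where stated.

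Genes were named by a rule, from probe sets with exactly 1 gene that has a locus name and with no sign of cross-hybridization in the probe set's type. For fasting and for the difference it names the 10 largest called changes per direction, and for the sex comparisons the 6 largest, where the higher group mean lies above the 60th percentile (log2 7.73) and, except for the difference, the arrays of the groups do not overlap. It adds up to 4 called members of each called list, and the genes fixed for every comparison (acs-2, lipl-4, fat-7, icl-1, sod-3 and vit-2 for fasting, vit-2, rme-2, spe-9 and lov-1 for sex). The rule names 360 genes in 611 pairs of gene and comparison, of which 601 were called. The text prints 144 of these genes, namely the largest changes, the fixed genes, and the members of called lists with the largest changes. How many members per list are printed was set after the values were seen, without regard to the alternatives. Of the 601 calls 490 were kept in every alternative that tested the gene, the 2-fold minimum left out.

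Samples with the same replicate number were checked for pairing by correlating their deviations from the group means across probe sets. In hermaphrodites r was 0.189, 0.129 and 0.259 between fed and fasted arrays, and in males 0.157, 0.119 and 0.274, all above 0.1. Between the sexes it was 0.0817, 0.0802 and 0.204 in fed and 0.133, 0.0525 and 0.197 in fasted worms. Arrays of the same number therefore paired in the fasting comparisons, and the fit with a replicate block is given as an alternative. Member counts of lists are from the fit without the block unless stated.

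Alternatives were pseudocounts of 64.6 (40th percentile of the signal) and 20.0 (20th percentile), no filter, a stricter filter at the 60th percentile, quantile normalization, median centring, scaling on 18 hybridization control probe sets, eBayes without the trend, array weights, only the arrays compared, the replicate block, a 2-fold minimum, fry, camera with an estimated correlation, and leaving out each array in turn. The pseudocount at the 20th percentile was chosen after seeing the data. For the difference and the overlap, fed and fasted were also exchanged within same-numbered pairs under the replicate block, a test added after the values were seen. Simulated data with 200 changed probe sets were fitted. Of added changes of 0.5, 1 and 2 log2 the fit recovered 2.99%, 50.7% and 84.8% in hermaphrodites, 5.97%, 32.8% and 84.8% in males, and 0%, 10.4% and 63.6% for the difference, with 4 false calls of 96, 5 of 87 and 2 of 51. A shifted list of 20 genes was found each time and no unchanged list called, which is no test of real lists. Probe sets without exactly 1 gene were only counted.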

Results

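Transcript levels in whole worms of the wild-type strain N2 of Caenorhabditis elegans were measured on 12 Affymetrix arrays, 1 array per RNA sample. Hermaphrodites, which make both sperm and oocytes, and males were kept fed or were deprived of food for 48 h from day 2 of adulthood, and every sample was collected on day 4. This gave 4 groups of 3 arrays, and the labels describe 3 independent experiments that each supplied 1 sample per group. All worms were on 5-fluoro-2'-deoxyuridine (FUdR), a blocker of DNA synthesis that keeps progeny from hatching. The comparisons ask what fasting changed in each sex, whether the changes differed between the sexes, and how the sexes differed when fed and when fasted. Levels and changes are on the log2 scale of the deposited signal, with SD or standard error (SE) and n = 3 arrays per group. The number of arrays limits precision, since arrays hold no read depth.

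Sex separated the arrays more than feeding did. The first principal component held 83.0% of the variance and parted hermaphrodites from males, and the second held 6.82% and parted fed from fasted worms in both sexes. Levels across probe sets correlated at r = 0.957 to 0.975 between arrays of the same group. The mean r of arrays was 0.937 between fed and fasted hermaphrodites and 0.506 between fed hermaphrodites and fed males, across probe sets, which are not independent replicates. As a check of the sex labels, the yolk protein gene vit-2 stood at 14.09 ± 0.16 in fed hermaphrodites and 7.38 ± 0.71 in fed males, and rme-2, the yolk receptor of oocytes, at 12.76 ± 0.07 and 6.79 ± 0.11. The male sensory neuron gene lov-1 stood at 3.45 ± 2.65 in fed hermaphrodites and 7.74 ± 0.13 in fed males, and the sperm gene spe-9 at 4.74 ± 0.80 and 6.34 ± 0.33.

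In hermaphrodites, fasting raised genes such as hsp-12.6 and hsp-12.3 (DAF-16 targets), acs-2 and lipl-4. The fatty acid oxidation and lipolysis lists did not pass. Collagen, digestive protease and lysozyme lists fell, with adjusted p of 0.0506, 0.0329 and 0.0652 with an estimated correlation. The small heat shock genes hsp-12.6 and hsp-12.3 rose by 6.58 ± 0.85 and 5.31 ± 0.24 (SE), and acs-2, an acyl-CoA synthetase gene of mitochondrial fatty acid oxidation, rose by 4.77 ± 0.54, from 6.42 ± 0.22 to 11.19 ± 1.41 (SD, n = 3). The lysosomal lipase gene lipl-4 rose by 2.72 ± 0.38, while fat-7, a stearoyl-CoA desaturase gene, changed by -1.50 ± 0.22 (adjusted p = 7.32e-04). Among the other large rises were clec-61, a C-type lectin gene (5.95 ± 0.52), the lysozyme gene ilys-3 (5.18 ± 0.64), the alcohol dehydrogenase gene adh-1 (3.90 ± 0.21), the aquaporin gene aqp-1 (3.75 ± 0.29), the fatty acid and retinol binding protein gene far-7 (3.57 ± 0.20) and the linker histone gene hil-1 (2.81 ± 0.15). Adjusted p lay between 1.69e-07 and 4.32e-04 for these 10 rises. The largest falls were sysm-1 (-6.19 ± 0.47), the folate transporter family gene folt-2 (-5.66 ± 0.56), the lysozyme gene ilys-5 (-5.64 ± 0.25), ctsa-1.2 (-5.48 ± 0.32), bcf-1 (-5.25 ± 0.31), hrg-11.2 (-4.71 ± 0.32), the inositol transporter gene hmit-1.1 (-4.49 ± 0.43), the infection response gene irg-8 (-4.47 ± 0.24), dod-19 (-4.45 ± 0.27) and the insulin-like peptide gene ins-7 (-4.37 ± 0.29). Their adjusted p lay between 1.69e-07 and 2.53e-05.

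A total of 1816 of 15913 probe sets changed in hermaphrodites (11.4%; limma, Benjamini-Hochberg adjusted), of which 910 rose and 906 fell. The split was 733 and 969 after median centring, 742 and 885 after quantile normalization and 678 and 766 on hybridization controls. It was 537 and 816 without fasted replicate 2 and 532 and 825 without 3. The replicate block gave 2495, 1399 rises and 1096 falls. The 1816 stood for 1561 genes, and 344 rises and 655 falls reached 2-fold. The glyoxylate cycle gene icl-1 rose by 0.90 ± 0.23 (adjusted p = 0.0265) and the superoxide dismutase gene sod-3 by 0.93 ± 0.25 (adjusted p = 0.0318), while vit-2 changed by -0.32 ± 0.28 (adjusted p = 0.537). The icl-1 call ended without fed replicate 1 (adjusted p = 0.0529), fed replicate 2 (0.0984) or fasted replicate 1 (0.0695), after median centring (0.0523), without the variance trend (0.0533) and with only the arrays compared (0.06), and other probe sets of icl-1 gave 0.95 (0.0476) and 0.71 (0.097). That of sod-3 ended without fed replicate 1 (0.121), fed replicate 2 (0.0639) or fasted replicate 3 (0.122), after quantile normalization (0.0846), without the trend (0.0523) and with only the arrays compared (0.0506). Fed levels of hsp-12.6 lay near the lower end of the scale (2.46), and its rise was 4.31 with a pseudocount at the 20th percentile and 3.03 with one at the 40th. With the higher one the rises of clec-61 and lipl-4 were 3.60 and 1.76, and the change of hmit-1.1 was -2.90.

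**Figure D1:**
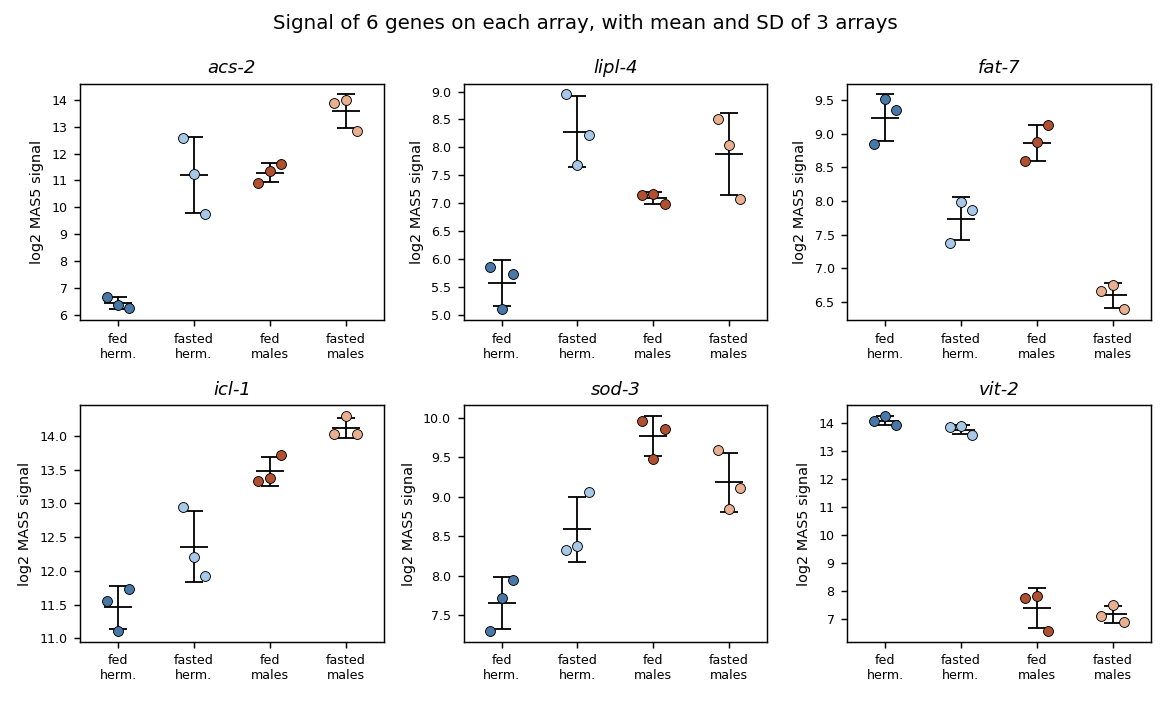
Log2 signal (vertical axis) of acs-2, lipl-4, fat-7, icl-1, sod-3 and vit-2 on each of the 12 arrays by group (horizontal axis), with the group mean and SD of 3 arrays. The acs-2 signal rises from a mean of 6.42 to 11.19 in hermaphrodites and from 11.29 to 13.57 in males.

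By the camera test 12 lists were lower and 3 higher in fasted hermaphrodites, and 2 of these 15 kept their call with an estimated correlation. Of 82 cuticle collagen genes 39 fell and none rose (46 fell when adjusted over the list alone, median -1.42), among them col-183 (-3.85 ± 0.41) and col-143 (-3.84 ± 0.49). Of 16 intestinal protease genes 12 fell (12 over the list alone, where 1 also rose, median -0.93), led by the cathepsin B-like genes cpr-4 (-3.04 ± 0.31) and cpr-1 (-2.68 ± 0.24). Of 36 lysozyme and antimicrobial peptide genes 19 fell and 4 rose (20 and 6 over the list alone, median -0.79), and of 137 C-type lectin genes 27 fell and 6 rose (28 and 11, median -0.09), with clec-67 at -3.96 ± 0.27. Among detoxification genes, 11 of 33 glutathione S-transferase genes fell and 2 rose (15 and 2 over the list alone, median -0.47), with gst-10 at -2.27 ± 0.37 and gst-40 at 2.56 ± 0.50. Of 53 UDP-glucuronosyltransferase genes 17 fell and 8 rose (19 and 9, median -0.15), with ugt-26 at -2.77 ± 0.14 and ugt-36 at 2.80 ± 0.33. The camera adjusted p was 7.09e-23 for collagens, 6.15e-11 for proteases, 1.25e-07 for lysozymes, 0.002 for lectins, 1.03e-04 for glutathione S-transferases and 0.002 for UDP-glucuronosyltransferases. With an estimated correlation the adjusted p was 0.0506 for collagens, 0.0329 for proteases, 0.0652 for lysozymes, 0.069 for lectins, 0.267 for glutathione S-transferases and 0.329 for UDP-glucuronosyltransferases. A dimmer probe set of gst-40 gave -0.24, and with the pseudocounts at the 40th and 20th percentiles gst-40 changed by 0.74 and 1.38, ugt-36 by 0.66 and 1.34, and clec-67 by -2.58 at the 40th.

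Tissue markers were measured beside these groups in hermaphrodites, and of them the intestine list alone kept its call with an estimated correlation. Of 18 body wall muscle genes 7 fell (8 over the list alone, median -0.55; camera adjusted p = 1.03e-05; adjusted p = 0.238 with an estimated correlation), among them the myosin gene unc-54 (-1.303 ± 0.18) and the troponin T gene mup-2 (-1.27 ± 0.18). Of 14 intestine markers, which hold cpr-1 and asp-1 of the protease list, 7 fell and 1 rose (8 and 2 over the list alone, median -0.61; adjusted p = 4.12e-05, and 0.0329 with an estimated correlation), with the aspartic protease gene asp-1 at -2.12 ± 0.16. Of 50 sperm genes 2 fell (none over the list alone, median -0.91; adjusted p = 1.60e-04; adjusted p = 0.458 with an estimated correlation), spe-11 (-2.39 ± 0.71, adjusted p = 0.0492) and spe-44 (-0.55 ± 0.14, adjusted p = 0.0279). The sperm median was -0.10 (adjusted p = 0.326) without fed replicate 1. None of 23 oogenesis and maternal genes was called, by either adjustment, while their median was -0.15 (adjusted p = 0.0333; adjusted p = 0.309 with an estimated correlation). The oogenesis call ended after quantile normalization (0.268), with the stricter filter (0.066), on hybridization controls (0.0542) and without fed replicate 2 (0.0809) or 3 (0.061) and fasted replicate 2 (0.0954) or 3 (0.11). The spe-11 call ended without any 1 array except fasted replicate 3 (adjusted p from 0.0612 to 0.187), without which it was -3.60, and that of spe-44 without fed replicate 1 (0.1) or 3 (0.0944) and fasted replicate 1 (0.077) or 2 (0.0889). With the pseudocounts at the 40th and 20th percentiles spe-11 was at -0.54 and -1.09 (adjusted p = 0.0827 and 0.0502).

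The vacuolar ATPase and yolk lists were near the threshold in hermaphrodites. Of 18 vacuolar ATPase genes 2 fell (4 fell and 1 rose over the list alone, median -0.10; adjusted p = 0.0376; adjusted p = 0.176 with an estimated correlation), vha-12 (-0.69 ± 0.13) and vha-13 (-0.37 ± 0.11, adjusted p = 0.0463). Other probe sets of vha-13 gave 0.20 and -0.12 (0.934). Of 5 vitellogenin genes 1 fell (1 over the list alone, median -0.39; adjusted p = 0.0416; adjusted p = 0.401 with an estimated correlation), vit-1 (-2.29 ± 0.58, adjusted p = 0.0222). Both list calls ended after quantile normalization (0.0976 and 0.128), with the stricter filter (0.0697 each), on hybridization controls (0.0719 and 0.0542) and without single arrays. The vitellogenin call also ended without the trend (0.0547) and with array weights (0.0574). For the vacuolar ATPase these were fed replicate 1 (0.065) or 3 (0.0842) and fasted replicate 2 (0.0844) or 3 (0.0573), and for the vitellogenins any 1 of the 6 hermaphrodite arrays (0.0588 to 0.0854). The vit-1 call ended without any 1 hermaphrodite array except fed replicate 3 (0.0528 to 0.0742). That of vha-13 ended without any 1 hermaphrodite array, male fed replicate 2 or male fasted replicate 3 (0.053 to 0.144), and on the hybridization control scale (0.236).

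Lists that rose in hermaphrodites were the respiratory chain, nuclear hormone receptors and targets of the transcription factor DAF-16. Of 31 respiratory chain genes 7 rose and none fell (13 over the list alone, median 0.25), with the succinate dehydrogenase gene sdha-1 at 0.65 ± 0.15 and the complex III gene ucr-2.1 at 0.51 ± 0.13. Of 152 nuclear hormone receptor genes 8 rose and 1 fell (4 rose over the list alone, median 0.29), with nhr-18 at 1.47 ± 0.23 and nhr-105 at 1.096 ± 0.26. Of 13 DAF-16 targets 5 rose and 1 fell (6 and 1 over the list alone, median 0.47), hsp-12.6 and hsp-12.3 among the risen. With the replicate block 12 respiratory chain genes, 20 receptors and 6 DAF-16 targets rose. The camera adjusted p was 1.49e-05 for the respiratory chain, 0.002 for the receptors and 0.011 for the DAF-16 targets, and with an estimated correlation the adjusted p was 0.234, 0.298 and 0.391. The sdha-1 call ended after quantile normalization (0.0535), and another of its probe sets gave 0.10 (0.895). That of ucr-2.1 ended without fed replicate 1 (0.0691) or 2 (0.0963) and fasted replicate 2 (0.0875) or 3 (0.0982), and that of nhr-105 without fed replicate 2 (0.06) or 3 (0.0594) and fasted replicate 2 (0.0664).

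The other 20 lists did not pass the test in hermaphrodites, with adjusted p from 0.0617 for autophagy to 0.920 for cytochrome P450. With the replicate block the autophagy list had an adjusted p of 0.0233, and 3 of its 27 genes rose. It also passed with the pseudocount at the 40th percentile (0.0449), no filter (0.0396), quantile normalization (0.03) and array weights (0.0346), and without fed replicate 3 (0.029) or male fasted replicates 2 (0.0498) or 3 (0.0391), hypodermis markers without male fasted replicate 3 (0.0332), and ribosomal genes without fasted replicate 2 (0.0265). In lists of fat and sugar metabolism, 2 of 10 lipolysis genes rose and 1 fell, 2 of 25 fatty acid oxidation genes rose and 3 fell, 1 of 22 fatty acid synthesis genes rose and 3 fell, 2 of 8 glyoxylate cycle genes rose, 1 of 16 glycolysis genes rose, and 2 of 8 trehalose genes rose and 1 fell. The SCF ubiquitin ligase list passed with the pseudocounts at the 40th (8.81e-04) and 20th percentile (0.0054), no filter (0.0396) and median centring (0.0499). The embryonic list passed with the first 3 of these (0.021, 0.0328 and 0.0326) and the proteasome after quantile normalization (0.0267). Of 199 SCF genes 7 rose (16 with the replicate block) and 5 fell, of 13 heat shock genes 1 rose and 2 fell. Of 17 antioxidant genes 2 rose and 1 fell, of 55 cytochrome P450 genes 7 rose and 7 fell, and of 20 insulin-like peptide genes 3 rose and 1 fell. None of 31 proteasome genes or 61 ribosomal protein genes was called, and 1 of 29 DNA replication genes fell. Among markers, 4 of 14 hypodermis genes fell, 2 of 19 neuron genes rose, 1 of 7 embryonic genes rose, 1 of 12 male somatic genes fell and none of 13 pharynx genes was called. Median, mean and test differed in sign for lipolysis, fatty acid oxidation, fatty acid synthesis, heat shock and cytochrome P450 genes.

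**Figure D2:**
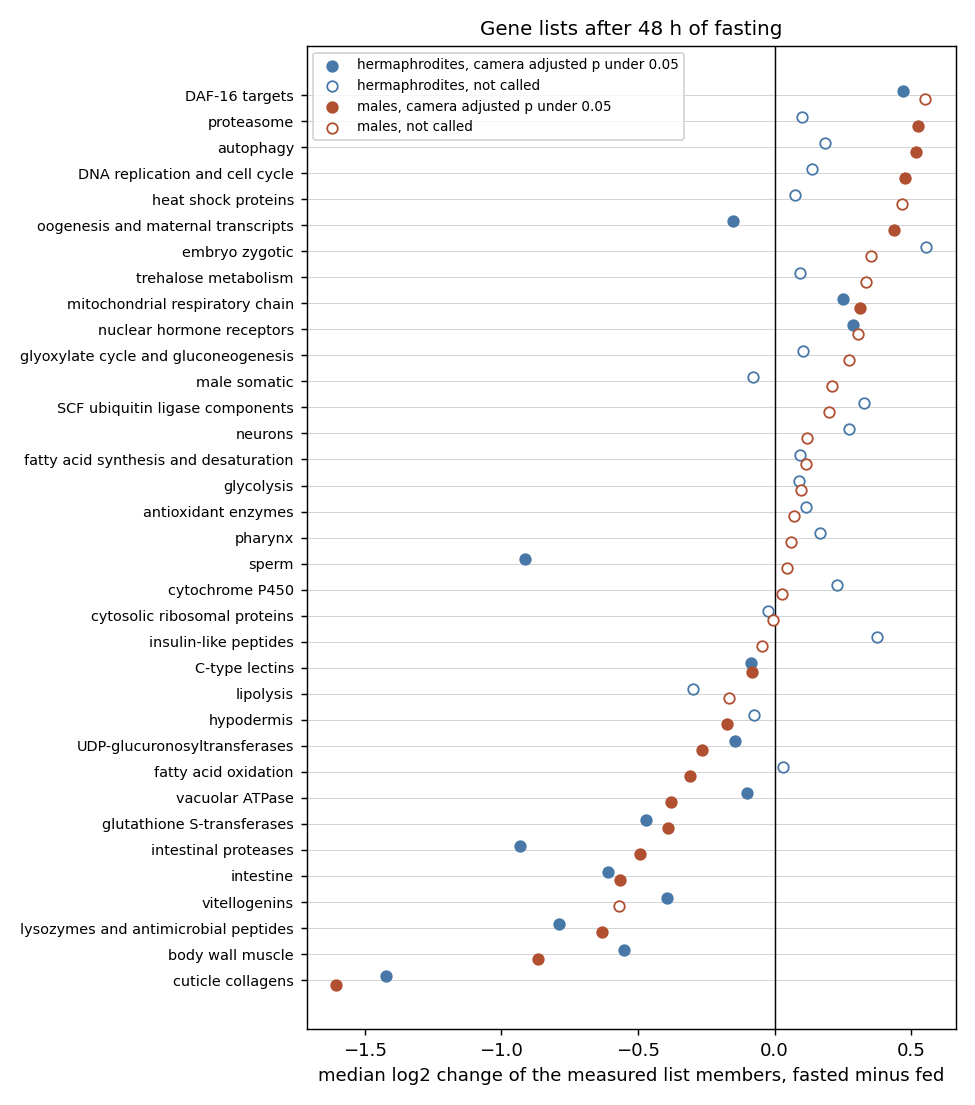
Median log2 change after fasting (horizontal axis, fasted minus fed) of the measured members of each of 35 gene lists (vertical axis) in hermaphrodites and males, with filled points for a camera adjusted p under 0.05. Cuticle collagens lie lowest, at -1.42 in hermaphrodites and -1.60 in males, and the ribosomal protein medians (-0.02 and -0.00) turn positive after quantile normalization.

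In males, fasting changed 4352 probe sets against 1816 in hermaphrodites. DNA replication genes rose as a list, and collagen, muscle and lysozyme genes fell. The proteasome and autophagy lists also rose and the glutathione S-transferases fell, with adjusted p of 0.249, 0.165 and 0.0716 with an estimated correlation, and after median centring 6 of 31 proteasome and 5 of 27 autophagy genes rose. The small heat shock gene hsp-12.6 rose by 6.36 ± 0.85 and hsp-16.20 by 3.75 ± 0.84. Other large rises were zig-3, which encodes a secreted immunoglobulin domain protein (3.71 ± 0.29), ilys-3 (3.63 ± 0.64), hil-1 (3.42 ± 0.15), the fatty acid oxidation gene hacd-1 (3.27 ± 0.46), far-7 (3.18 ± 0.20), srap-1 (3.09 ± 0.32), the acyl-CoA synthetase gene acs-11 (3.08 ± 0.37) and the S-adenosylmethionine synthetase gene sams-5 (2.83 ± 0.48). Their adjusted p lay between 8.59e-08 and 0.0057. The largest falls were sysm-1 (-7.10 ± 0.47), irg-5 (-5.98 ± 0.23), sdz-6 (-5.84 ± 0.69), ilys-5 (-5.65 ± 0.25), folt-2 (-5.51 ± 0.56), bcf-1 (-5.40 ± 0.31), the claudin-like gene clc-11 (-5.40 ± 0.80), the collagen genes col-80 (-5.29 ± 0.49) and col-158 (-5.21 ± 0.66) and drd-50 (-5.24 ± 0.29), with adjusted p between 5.31e-08 and 4.24e-04. The acs-2 gene rose by 2.28 ± 0.54 (adjusted p = 0.0077), from 11.29 ± 0.36 to 13.57 ± 0.64 (SD, n = 3), while another of its probe sets gave 1.08 (adjusted p = 0.177), and fat-7 changed by -2.26 ± 0.22 (adjusted p = 2.27e-05). With the pseudocount at the 40th percentile hsp-12.6 rose by 3.42 and hsp-16.20 by 2.29, and sdz-6, clc-11 and col-158 changed by -2.33, -2.63 and -2.35. With the one at the 20th, sdz-6 and col-158 changed by -3.55 and -3.45.

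A total of 4352 probe sets changed in males (27.3%; limma, Benjamini-Hochberg adjusted), standing for 3670 genes. Of the probe sets 3029 rose and 1323 fell. The block gave 5327, of which 3814 rose. At 2-fold or more there were 666 rises and 829 falls. The median change of all genes was 0.24 in males and 0.09 in hermaphrodites. Under median centring, quantile normalization and scaling on hybridization controls it was 0.02, 0.11 and 0.31 in males, and rises made up 41.9%, 56.7% and 73.3% of the calls against 69.6% on the deposited scale. Median changes of the lists in males are therefore also given relative to all genes. Among the fixed genes, lipl-4 changed by 0.78 ± 0.38 (adjusted p = 0.156), icl-1 by 0.64 ± 0.23 (0.0604), sod-3 by -0.58 ± 0.25 (0.109) and vit-2 by -0.22 ± 0.28 (0.618). Leaving out 1 array brought lipl-4 past the threshold without fasted replicate 3 (1.18, adjusted p = 0.0326), vit-2 without fed replicate 3 (-0.63, 0.0235) and sod-3 without fasted replicate 1 (-0.79, 0.0486). It did so for icl-1 without hermaphrodite fasted replicate 1 (0.0174) or 3 (0.0418).

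Cuticle collagens fell most among the lists in males. Of 82 collagen genes 48 fell and none rose (54 fell when adjusted over the list alone, median -1.60, or -1.84 relative to all genes; camera adjusted p = 2.48e-31, and 0.0161 with an estimated correlation). Of 18 body wall muscle markers 12 fell (14 over the list alone, median -0.86, relative -1.101, adjusted p = 4.80e-15, and 0.0256 with an estimated correlation), with the troponin T genes tnt-2 and mup-2 at -2.15 ± 0.23 and -2.0996 ± 0.18. Of 14 hypodermis markers 5 fell (5 over the list alone, median -0.17, relative -0.41, adjusted p = 0.0148; adjusted p = 0.0716 with an estimated correlation), with the collagen gene col-19 at -2.02 ± 0.52 and the GATA factor gene elt-3 at -0.61 ± 0.14. The col-19 change was -1.16 without fasted replicate 3, and another probe set of elt-3 gave -0.45 (0.0523). Of 14 intestine markers 6 fell and 1 rose (7 and 1, median -0.57, relative -0.80, adjusted p = 4.50e-05, and 0.0161 with an estimated correlation), among them the intestinal actin gene act-5 (-1.84 ± 0.15) and the acid phosphatase gene pho-1 (-1.55 ± 0.32).

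Digestive, lectin and detoxification lists also fell in males, of which the proteases, lysozymes and lectins kept their calls with an estimated correlation. Of 16 intestinal protease genes 9 fell and 1 rose (9 and 1 over the list alone, median -0.49, relative -0.73), with the aspartic protease genes asp-14 and asp-13 at -4.001 ± 0.33 and -3.01 ± 0.33. Of 36 lysozyme and antimicrobial peptide genes 16 fell and 3 rose (17 and 3, median -0.63, relative -0.87), with spp-23 at -4.43 ± 0.49. Of 137 C-type lectin genes 32 fell and 16 rose (32 and 16, median -0.08, relative -0.32), with clec-3 and clec-64 at -4.02 ± 0.58 and -4.01 ± 0.63. Of 33 glutathione S-transferase genes 12 fell (14 fell and 1 rose over the list alone, median -0.39, relative -0.62), with gst-10 and gst-19 at -3.53 ± 0.37 and -3.23 ± 0.35. Of 53 UDP-glucuronosyltransferase genes 19 fell and 8 rose (20 and 10, median -0.27, relative -0.50), with ugt-26 and ugt-14 at -3.14 ± 0.14 and -3.07 ± 0.44. The camera adjusted p was 1.95e-05 for proteases, 5.94e-09 for lysozymes, 2.81e-05 for lectins, 5.94e-09 for glutathione S-transferases and 7.25e-07 for UDP-glucuronosyltransferases. The adjusted p with an estimated correlation was 0.0456, 0.0256, 0.0161, 0.0716 and 0.107 in the same order. The changes of gst-19 and clec-64 were -1.82 and -2.102 with the pseudocount at the 40th percentile.

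Fatty acid oxidation and vacuolar ATPase genes fell in males. Of 25 fatty acid oxidation genes 9 fell and 2 rose (9 and 2 over the list alone, median -0.31, relative -0.54, camera adjusted p = 1.33e-04, and 0.0161 with an estimated correlation), and the acyl-CoA dehydrogenase gene acdh-1 fell most among them (-3.20 ± 0.58). Members that went against the list were acs-2 and hacd-1. Of 18 vacuolar ATPase genes 9 fell and 1 rose (11 and 1, median -0.38, relative -0.62, adjusted p = 5.95e-08, and 0.0088 with an estimated correlation), with vha-19 at -1.23 ± 0.13 and vha-12 at -1.13 ± 0.13.

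Proteasome, autophagy, DNA replication, respiratory chain and oogenesis lists rose in males, and DNA replication alone kept its call with an estimated correlation. Of 31 proteasome genes 22 rose and none fell (27 over the list alone, median 0.52, relative 0.29), with the regulatory particle genes rpn-9 and rpt-1 at 0.75 ± 0.13 and 0.74 ± 0.13. Of 27 autophagy genes 10 rose (10 over the list alone, median 0.52, relative 0.28), with epg-6 at 1.201 ± 0.11 and epg-4 at 0.97 ± 0.18. Of 29 DNA replication and cell cycle genes 17 rose (20 over the list alone, median 0.48, relative 0.24), with the helicase gene mcm-6 at 0.95 ± 0.11 and the ribonucleotide reductase gene rnr-1 at 0.89 ± 0.16. Of 31 respiratory chain genes 13 rose (18 over the list alone, median 0.31, relative 0.08), with ucr-2.3 at 0.51 ± 0.15 (adjusted p = 0.0207) and the complex I gene nuo-6 at 0.47 ± 0.16 (adjusted p = 0.0494). Of 23 oogenesis and maternal genes 9 rose and 2 fell (12 and 2, median 0.44, relative 0.20), with mex-6, which acts in embryo polarity, at 1.202 ± 0.15 and the eggshell gene perm-2 at -1.39 ± 0.13. The camera adjusted p was 7.25e-07 for the proteasome, 9.41e-04 for autophagy, 4.19e-05 for DNA replication, 0.0048 for the respiratory chain and 0.026 for oogenesis. Estimating the correlation gave an adjusted p of 0.249, 0.165, 0.0256, 0.336 and 0.249 in the same order.

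Scaling bore on these rises in males. After median centring 6 of the 31 proteasome genes, 5 of the 27 autophagy genes, 7 of the 29 DNA replication genes, 6 of the 23 oogenesis genes and 0 of the 31 respiratory chain genes rose, and the respiratory chain call ended (adjusted p = 0.265). The oogenesis call ended after quantile normalization (0.0705), with the stricter filter (0.0721) and with pseudocounts at the 40th and 20th percentiles (0.109 and 0.0544). The ucr-2.3 change was 0.30 after median centring (adjusted p = 0.240), and its call ended without fed replicate 3 (0.0769) and fasted replicate 2 (0.0754) or 3 (0.066). That of nuo-6 (0.26 after centring, 0.341) ended without any 1 array except hermaphrodite fed replicates 1 and 3 and male fasted replicate 3 (0.0579 to 0.182).

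The remaining 19 lists did not pass the test in males, with adjusted p from 0.0545 for DAF-16 targets to 0.949 for the glyoxylate cycle. With the replicate block the DAF-16 targets, of which 7 of 13 rose with it and 5 without, had an adjusted p of 0.0432. They also passed with no filter (0.0111), quantile normalization (0.0118), median centring (0.0148), hybridization controls (0.0326), array weights (0.0423), the pseudocount at the 20th percentile (0.0464) and without fed replicate 3 (0.0124) or fasted replicate 2 (0.029). Their call is not settled. So did the vitellogenins without the same arrays (0.0128 and 0.0302), ribosomal and cytochrome P450 genes without fed replicate 1 (3.38e-04 and 0.0486) or fasted replicate 2 (0.0115 and 0.0495), and insulin-like peptides without fasted replicate 3 (0.0336) or with the stricter filter (0.005). Of 10 lipolysis genes 3 rose and 3 fell, of 22 fatty acid synthesis genes 5 rose and 2 fell, of 8 glyoxylate cycle genes 2 rose and 2 fell, of 16 glycolysis genes 4 rose, and of 8 trehalose genes 3 rose. Of 199 SCF ubiquitin ligase genes 31 rose and 10 fell, and of 152 nuclear hormone receptor genes 26 and 6. Of 55 cytochrome P450 genes 10 rose and 12 fell, and of 20 insulin-like peptide genes 1 and 5. Of 13 heat shock genes 5 rose and 2 fell, of 17 antioxidant genes 3 and 2, and of 5 vitellogenin genes 1 fell. None of 61 ribosomal protein genes was called. Their list passed after quantile normalization (0.0373, 6 rose, median 0.08) and median centring (2.31e-05, 3 fell, median -0.22). Of the markers, 1 of 50 sperm and 1 of 19 neuron genes rose, 1 of 12 male somatic genes fell, and none of 13 pharynx or 7 embryonic genes changed. Median, mean and test differed in sign for lipolysis, fatty acid synthesis, glyoxylate cycle, ribosomal, SCF, antioxidant, cytochrome P450, sperm, male somatic, pharynx and neuron genes.

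The fasting changes of the sexes shared many probe sets. A total of 428 probe sets rose and 655 fell in both sexes, where independent lists of these sizes would share 173 and 75.3. Shared rises and falls were 242 and 734 after median centring, 378 and 647 after quantile normalization, 339 and 555 on hybridization controls and 716 and 754 with the replicate block. Only 32 were called in opposite directions, 11 higher in hermaphrodites and lower in males and 21 the other way, against 75.7 and 172 for independent lists. Of the probe sets called in both sexes 97.1% went the same way. The genes hsp-12.6, ilys-3, hil-1 and far-7 were among the largest rises in both sexes, and sysm-1, ilys-5, folt-2 and bcf-1 among the largest falls. Across all tested probe sets the changes correlated at r = 0.546 (Spearman's rho = 0.305), and 88.7% of the probe sets called in hermaphrodites had the same sign in males. The fasting comparisons of the sexes share no arrays, and probe sets are not independent replicates.

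**Figure D3:**
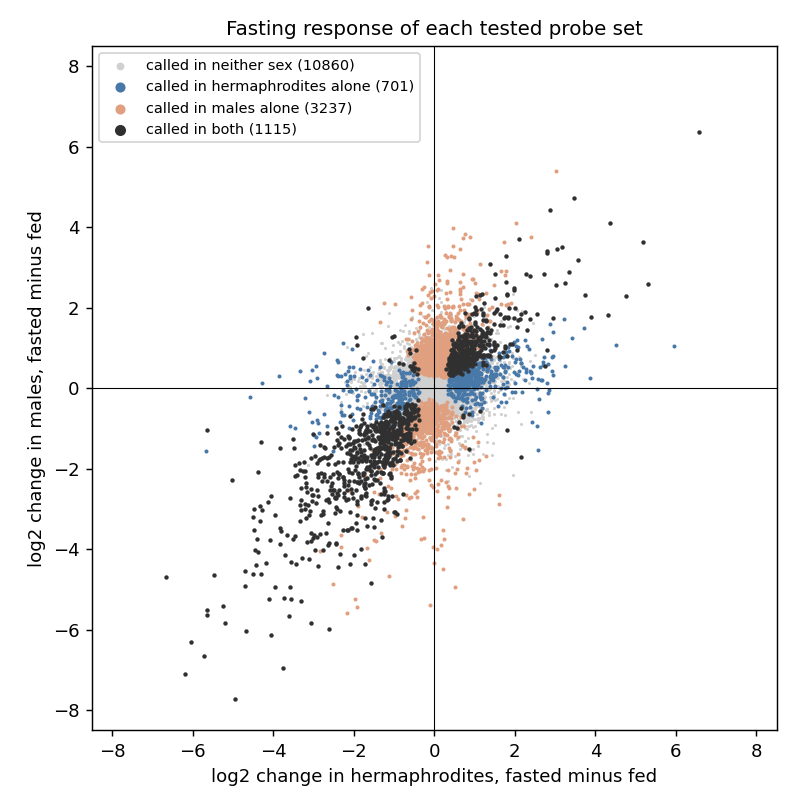
Log2 change after fasting in hermaphrodites (horizontal axis) and males (vertical axis) for each of 15913 probe sets, coloured by the sex in which it passed an adjusted p of 0.05. Of these, 1115 passed in both sexes, 701 in hermaphrodites alone, 3237 in males alone and 10860 in neither.

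The fasting response differed between the sexes for 840 probe sets, 232 with a higher and 608 with a lower change in hermaphrodites than in males (limma interaction, Benjamini-Hochberg adjusted). Differences below are the hermaphrodite change minus the male change. The sphingomyelinase gene asm-3 differed by 5.46 ± 1.13 (0.52 in hermaphrodites, -4.93 in males), clc-11 by 5.29 ± 1.13 (-0.10 and -5.40) and clec-61 by 4.91 ± 0.74 (5.95 and 1.03). On the other side, the protease genes cpr-4 and cpr-5 differed by -3.48 ± 0.44 (-3.04 and 0.44) and -3.22 ± 0.51 (-1.95 and 1.27), and the lysosomal lipase gene lipl-1 by -3.07 ± 0.63 (-0.97 and 2.099). Further positive differences were clec-183 (4.49 ± 0.85), clec-64 (4.07 ± 0.90), col-129 (4.05 ± 1.04), hsd-2 (3.75 ± 0.42), the infection response genes irg-5 (3.37 ± 0.33) and irg-4 (3.25 ± 0.65), and clx-1 (3.25 ± 0.68). Further negative differences were cyp-13A5 (-3.39 ± 0.88), lips-11 (-2.99 ± 0.44), cnc-6 (-2.95 ± 0.68), dscc-1 (-2.93 ± 0.72), tag-164 (-2.58 ± 0.63), clec-54 (-2.57 ± 0.27) and rcd-1 (-2.51 ± 0.26). Adjusted p for these 20 genes lay between 6.44e-04 for irg-5 and 0.0456 for cyp-13A5.

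Some of these differences depended on 1 array or on dim values. The call of asm-3 ended without male fed replicate 1 (adjusted p = 0.0515), that of clc-11 without hermaphrodite fed replicate 1 (0.0504), fasted replicates 2 (0.0561) or 3 (0.0504) or male fed replicate 2 (0.0538), and that of clec-64 without hermaphrodite fasted replicate 3 (0.0513) or male fed replicates 1 (0.0522), 2 (0.0612) or 3 (0.0658). For col-129 it ended without any 1 array except hermaphrodite fed replicate 3, hermaphrodite fasted replicate 1 and male fasted replicate 1 (0.0628 to 0.099), and for cyp-13A5 without any 1 except hermaphrodite fed replicate 1 and the 3 male fed arrays (0.066 to 0.0999). The call of cnc-6 ended without any 1 array except hermaphrodite fed replicate 1, hermaphrodite fasted replicates 1 and 3, male fed replicate 3 and male fasted replicate 1 (0.0529 to 0.0689). That of dscc-1 was kept only without male fed replicate 1 (otherwise 0.0507 to 0.0831) and that of tag-164 only without hermaphrodite fed replicate 2 (0.06 to 0.0774). At the 40th percentile pseudocount the differences were 2.62 for asm-3, 2.59 for clc-11, 3.14 for clec-61, 2.097 for clec-64, 2.04 for col-129, 2.47 for hsd-2, 2.07 for clx-1, -1.18 for dscc-1, -0.84 for tag-164 and -1.66 for rcd-1. With the one at the 20th they were -1.90 for dscc-1 and -1.35 for tag-164.

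Of the fixed genes, sod-3 differed by 1.51 ± 0.36 (adjusted p = 0.0320). The differences of acs-2 (2.48 ± 0.76, adjusted p = 0.0781), lipl-4 (1.95 ± 0.54, 0.0565), fat-7 (0.76 ± 0.32, 0.177), icl-1 (0.26 ± 0.33, 0.705) and vit-2 (-0.09 ± 0.40, 0.927) did not pass. Another probe set of acs-2 differed by 3.42 (0.0289). With the replicate block 1641 probe sets were called, and acs-2 and lipl-4 had adjusted p of 0.0455 and 0.0253. Without hermaphrodite fasted replicate 3 acs-2 differed by 3.20 (0.0129), without male fasted replicate 1 lipl-4 differed by 2.26 (0.0358), and after quantile normalization fat-7 differed by 1.499 (0.0156). The sod-3 call ended without any 1 array except hermaphrodite fed replicate 3, hermaphrodite fasted replicate 1, male fed replicate 2 and male fasted replicate 1 (0.0516 to 0.0758). The median difference of all genes was -0.12, and 0.05, -0.04 and -0.16 under median centring, quantile normalization and hybridization control scaling. Higher hermaphrodite changes made up 27.6% of the calls, against 60.8%, 50.1% and 31.6% under these scalings.

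Among the lists, 7 had a higher and 4 a lower change in hermaphrodites than in males, and fatty acid oxidation and the vacuolar ATPase alone stayed called with an estimated correlation. Body wall muscle markers differed by a median of 0.55 (0.66 relative to all genes; 2 of 18 called, 6 over the list alone; camera adjusted p = 1.37e-06), with the myosin gene myo-3 at 1.39 ± 0.22. Fatty acid oxidation genes differed by 0.32 (relative 0.44, 2 of 25 called, 6 over the list alone; 3.07e-04), with the carnitine palmitoyltransferase family gene cpt-6 at 3.25 ± 0.40 and the enoyl-CoA hydratase gene ech-6 at 0.81 ± 0.15. Vacuolar ATPase genes differed by 0.34 (relative 0.46, 3 of 18 called, 7 up and 2 down over the list alone; 7.40e-05), with vha-19 at 0.92 ± 0.18 and vha-15 at 0.68 ± 0.17. Glutathione S-transferases differed by 0.42 (relative 0.54, 1 of 33 called, 4 over the list alone; 3.07e-04), with gst-24 at 1.40 ± 0.16, and UDP-glucuronosyltransferases by 0.24 (relative 0.36, 3 of 53 higher and 2 lower, 8 and 3 over the list alone; 0.0069), with ugt-18 at -2.31 ± 0.32 and ugt-36 at 1.85 ± 0.47. Cuticle collagens differed by 0.33 (relative 0.44, 4 of 82 higher and 1 lower, 4 and 1 over the list alone; 6.20e-04), with col-183 at -2.35 ± 0.58. Insulin-like peptides differed by 0.49 (relative 0.61, 1 of 20 higher and 2 lower, 3 and 2 over the list alone; 0.01), with ins-35 and ins-7 at -3.07 ± 0.52 and -2.28 ± 0.41. Under an estimated correlation the adjusted p was 0.0364 for these 2 and 0.193 to 0.453 for the other 5.

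Lists with a lower change in hermaphrodites were the proteasome, DNA replication, oogenesis and sperm lists. Proteasome genes differed by a median of -0.36 (relative -0.24, 4 of 31 called, 4 over the list alone; camera adjusted p = 4.20e-05), with rpt-1 and rpn-9 at -0.74 ± 0.18 and -0.70 ± 0.18. DNA replication genes differed by -0.41 (relative -0.30, 6 of 29 called, 9 over the list alone; 2.51e-04), with rnr-1 at -0.94 ± 0.23 and mcm-6 at -0.87 ± 0.16. Oogenesis genes differed by -0.65 (relative -0.54, 7 of 23 lower and 1 higher, 14 and 2 over the list alone; 1.13e-04), with mex-6 at -1.25 ± 0.22 and perm-2 at 1.43 ± 0.18. Sperm genes differed by -0.99 (relative -0.87, 1 of 50 called, 1 over the list alone; 0.0322), with spe-44 at -1.03 ± 0.20. With an estimated correlation the adjusted p was 0.0925 for DNA replication to 0.697 for sperm genes. The other 24 lists had adjusted p from 0.0664 for cytochrome P450 to 0.988 for fatty acid synthesis. Past the threshold without 1 array were cytochrome P450 (0.0476, 0.0379 and 0.0489 without hermaphrodite fed replicates 1 and 3 and fasted replicate 1, 0.0426 without male fasted replicate 2), autophagy (0.0432 without hermaphrodite fed replicate 1, 0.0265 without male fasted replicate 2) and ribosomal genes (0.0148 without male fed replicate 1). SCF genes passed with either pseudocount (0.0027 and 0.0109), autophagy with no filter (0.0136), proteases after quantile normalization (0.0275), ribosomal genes after median centring (0.0174) and cytochrome P450 on hybridization controls (0.0456). Median, mean and test differed in sign for lipolysis, glycolysis, ribosomal, respiratory chain, lectin, lysozyme, nuclear hormone receptor, male somatic and intestine genes.

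The sperm difference was -0.08 (adjusted p = 0.944) without hermaphrodite fed replicate 1, and its call also ended without hermaphrodite fasted replicate 2 (0.111) or 3 (0.134), male fed replicate 1 (0.0846) and male fasted replicate 2 (0.0773) or 3 (0.0898), and with the stricter filter (0.164). The collagen difference was 0.04 (0.116) without male fasted replicate 3, and that of insulin-like peptides was 0.48 (0.0505) without hermaphrodite fasted replicate 3. The call of rpt-1 ended without any 1 array except hermaphrodite fasted replicate 1 and male fasted replicate 1 (0.0511 to 0.0844; another of its probe sets gave -0.47, 0.209), and that of rpn-9 without any 1 except male fed replicate 3 and male fasted replicate 1 (0.0563 to 0.0927). For rnr-1 it was kept only without male fed replicate 3 (otherwise 0.051 to 0.0796), and for ugt-36 only without hermaphrodite or male fed replicate 1 (0.0636 to 0.0946). The vha-15 call ended without any 1 array except hermaphrodite fasted replicate 1, male fed replicate 2 and male fasted replicates 1 and 3 (0.0589 to 0.0896), and that of col-183 without any 1 except hermaphrodite fed replicate 2, hermaphrodite fasted replicate 3, male fed replicate 3 and male fasted replicate 3 (0.0655 to 0.087). The rpt-1, rpn-9 and rnr-1 calls also ended after median centring (0.119, 0.122 and 0.0865), and those of vha-19 and ech-6 on the hybridization control scale (0.0886 and 0.0742). After quantile normalization ech-6, gst-24 and col-183 differed by 0.38 (0.168), 0.76 (0.0175) and -1.53 (0.153). Under the pseudocount at the 40th percentile ugt-36 differed by 0.02 (0.972), ins-35 by -1.09 and ins-7 by -1.19, and with the one at the 20th ugt-36 differed by 0.51 (0.313) and ins-35 by -1.89.

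Between fed hermaphrodites and fed males, 11904 probe sets differed (74.8%). Of these 5713 were higher in hermaphrodites and 6191 in males, and 8761 differed by 2-fold or more. The larger side depends on the scaling, with 5977 higher and 5902 lower in hermaphrodites after median centring, 6059 and 5322 after quantile normalization and 6152 and 5178 on hybridization controls. Oogenesis and DNA replication genes were higher in hermaphrodites, and neuron and C-type lectin genes were higher in males. Values are hermaphrodite minus male. The uterine gene ule-4 was higher by 9.52 ± 0.80, the cell cycle phosphatase gene cdc-25.3 by 8.76 ± 0.53, the transthyretin-like gene ttr-50 by 8.54 ± 0.67, clec-222 by 8.40 ± 0.82, the yolk gene vit-1 by 8.36 ± 0.58 and the caveolin gene cav-1 by 8.23 ± 0.43. On the male side stood srlf-18 (-13.32 ± 0.23), srlf-11 (-11.999 ± 0.35), srlf-17 (-11.90 ± 0.17), clec-96 (-11.70 ± 0.61), clec-137 (-11.58 ± 0.84) and clec-197 (-11.33 ± 0.85). Adjusted p lay between 5.57e-13 and 1.33e-06. The fixed genes vit-2 (6.71 ± 0.28), rme-2 (5.98 ± 0.21), spe-9 (-1.60 ± 0.41) and lov-1 (-4.29 ± 0.95) had adjusted p from 1.76e-10 to 0.0033. Levels of the low sex were near the lower end of the scale for many of these genes (0.70 for srlf-18 in hermaphrodites). With the pseudocount at the 40th percentile cdc-25.3, ttr-50 and clec-222 were at 4.53, 5.02 and 4.19, srlf-18, srlf-11 and srlf-17 at -7.98, -6.62 and -7.54, spe-9 at -0.65 and lov-1 at -1.72. With the one at the 20th lov-1 was at -2.61, without hermaphrodite fed replicate 1 at -2.77, and after quantile normalization spe-9 was at -1.002.

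The vitellogenin, sperm and oogenesis lists had the largest medians between the fed sexes. All 23 oogenesis genes and all 29 DNA replication genes were higher in hermaphrodites, by adjustment over all genes and over the list alone (medians 5.28 and 3.28; camera adjusted p = 2.53e-14 and 1.00e-13, and 0.0052 and 0.003 with an estimated correlation), with the translational regulator gene puf-5 at 6.997 ± 0.27 and the cyclin E gene cye-1 at 5.78 ± 0.57. All 5 vitellogenin genes were higher (median 6.13; adjusted p = 6.53e-04). Of 50 sperm genes 48 were lower and 1 higher in hermaphrodites, by both adjustments (median -5.57; 6.87e-09), with ssp-35 at -7.68 ± 0.67, and all 12 male somatic genes were lower (median -3.98; 3.33e-04), with cwp-1 at -8.76 ± 0.65. The adjusted p with an estimated correlation was 0.197 for vitellogenins, 0.223 for sperm genes and 0.0922 for male somatic genes. The median difference of all genes was -0.20, and -0.12, -0.00 and 0.01 under median centring, quantile normalization and hybridization control scaling, so these medians relative to all genes were 5.48 for oogenesis, 3.48 for DNA replication, 6.33 for vitellogenins, -5.37 for sperm and -3.77 for male somatic genes. At the 40th percentile pseudocount cye-1 was at 2.48 and cwp-1 at -4.93, and with the one at the 20th cye-1 was at 3.74.

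Proteasome, SCF and autophagy genes were also higher in fed hermaphrodites. Of 31 proteasome genes 30 were higher (30 over the list alone, median 0.98, relative 1.18), with pas-7 at 2.55 ± 0.13. Of 199 SCF genes 49 were lower, 46 did not pass and the others were higher (49 lower and 105 higher over the list alone, median 1.05, relative 1.25), with skr-14 at 7.57 ± 0.75. Of 27 autophagy genes 15 were higher and 4 lower (15 and 4, median 0.70, relative 0.90), with epg-2 at 3.47 ± 0.29. The camera adjusted p was 8.15e-08, 0.0133 and 0.0202, and with an estimated correlation the adjusted p was 0.221, 0.223 and 0.272. With the stricter filter the SCF and autophagy calls ended (0.142 and 0.0601). Under the pseudocount at the 40th percentile skr-14 was at 3.88.

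Lists lower in fed hermaphrodites than in fed males included lectins, detoxification genes and markers of muscle, neurons, pharynx and intestine. Of 137 C-type lectin genes 108 were lower and 10 higher (110 and 10 over the list alone, median -2.42, relative -2.22, camera adjusted p = 2.85e-10, and 0.003 with an estimated correlation). Of 19 neuron markers 17 were lower (18, median -1.98, relative -1.77, 6.17e-05, and 0.0132 with an estimated correlation), with the synaptic vesicle gene rab-3 at -3.90 ± 0.16. Of 53 UDP-glucuronosyltransferase genes 42 were lower and 2 higher (43 and 2, relative median -1.08, 1.40e-05), with ugt-43 at -4.65 ± 0.23, of 33 glutathione S-transferases 20 were lower and 2 higher (20 and 2, relative -0.95, 0.0105), with gst-11 at -4.24 ± 0.71, and of 55 cytochrome P450 genes 33 were lower and 5 higher (33 and 5, relative -0.74, 0.012), with cyp-31A5 at 3.18 ± 0.24. Of 18 muscle markers 17 were lower (17, relative -1.32, 6.04e-05), with the titin gene ttn-1 at -2.17 ± 0.21, of 13 pharynx markers 9 (9, relative -1.04, 0.0178), with the myosin gene myo-2 at -3.20 ± 0.53, and of 14 intestine markers 10 (10, relative -0.63, 0.0246), with pho-1 at -2.03 ± 0.32. An estimated correlation gave the other 6 adjusted p of 0.17 to 0.317. At the 40th percentile pseudocount gst-11 was at -1.51 and myo-2 at -2.03, and at the 20th gst-11 at -2.50.

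Of 152 nuclear hormone receptor genes 88 were lower and 14 higher in fed hermaphrodites (86 and 14 over the list alone, relative median -0.57, camera adjusted p = 0.0023), with nhr-125 at -4.01 ± 0.41. Of 20 insulin-like peptide genes 17 were lower and 2 higher (17 and 2, relative -1.79, 0.0027), with ins-31 at -9.87 ± 0.50. Of 16 intestinal proteases 12 were lower (12, relative -0.62, 0.0152), with asp-14 at -3.30 ± 0.33, of 8 glyoxylate cycle genes 7 (7, relative -0.65, 0.0152), with the phosphoenolpyruvate carboxykinase gene pck-3 at -6.08 ± 0.33, and of 18 vacuolar ATPase genes 14 with 2 higher (14 and 2, relative -0.40, 0.0325), with vha-7 at 2.08 ± 0.16. Of 36 lysozyme and antimicrobial peptide genes 19 were lower and 3 higher (18 and 3, relative -0.55, 0.0434), with abf-1 at -6.88 ± 0.43. Of 82 collagens 33 were lower and 5 higher (30 and 4, relative -0.55, 0.0434), with dpy-14 at 4.63 ± 0.51. Of 61 ribosomal protein genes 24 were lower and 1 higher (10 and 1, median -0.27, relative -0.07, 0.0202), with rpl-11.2 at -0.79 ± 0.11, but after quantile normalization the median was 0.10 (adjusted p = 0.0665) with 16 higher and 1 lower, and rpl-11.2 was at -0.31. With an estimated correlation adjusted p of these 8 was 0.101 to 0.694. The other 11 lists had adjusted p from 0.0648 for fatty acid oxidation (0.0389 with no filter, 0.0476 with the stricter one, 0.0305 after quantile normalization, 0.0451 without hermaphrodite fasted replicate 3) to 0.672 for DAF-16 targets.

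Near the threshold in fed worms, leaving out 1 array ended the calls of ribosomal proteins (adjusted p = 0.0759 without hermaphrodite fed replicate 1, 0.0808 without male fed replicate 3), the vacuolar ATPase (0.0537 without hermaphrodite fed replicate 2) and lysozymes (0.0759 and 0.0729 without hermaphrodite fed replicates 1 and 2, 0.051 without hermaphrodite fasted replicate 2, 0.053 without male fed replicate 2). It ended that of collagens without any of the 3 hermaphrodite fed arrays, hermaphrodite fasted replicate 1 or male fed replicates 1 or 2 (0.051 to 0.0682). After quantile normalization the calls of proteases (0.0665), nuclear hormone receptors (0.0644), lysozymes (0.077) and collagens (0.195) ended. On hybridization controls those of the vacuolar ATPase (0.119), lysozymes (0.0531), collagens (0.0629) and ribosomal proteins (0.459, and 0.0639 after median centring) ended. Without the trend it was those of the vacuolar ATPase (0.051), lysozymes (0.0633) and collagens (0.051), with no filter those of lysozymes (0.0555) and collagens (0.091), and with the 2 pseudocounts those of the vacuolar ATPase (0.0594 and 0.0535) and lysozymes (0.0559 and 0.055). With the pseudocounts at the 40th and 20th percentiles pck-3 was at -2.65 and -3.95 and nhr-125 at -1.48 and -2.46, and at the 40th dpy-14 was at 2.81.

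Between fasted hermaphrodites and fasted males, 11245 probe sets differed (70.7%). Of these 5206 were higher in hermaphrodites and 6039 in males, and 7903 differed by 2-fold or more. Here too the side with more turned, with 6208 higher and 5065 lower after median centring, 5926 and 5005 after quantile normalization and 5587 and 5113 on hybridization controls. The neuropeptide-like gene nlp-39 was higher in hermaphrodites by 9.43 ± 0.43, sdz-25 by 8.75 ± 0.68, cav-1 by 7.94 ± 0.43, the zinc finger gene ztf-25 by 7.81 ± 0.38, the T-box gene sea-1 by 7.78 ± 0.76 and folt-3 by 7.75 ± 0.32. On the male side stood srlf-18 (-13.04 ± 0.23), srlf-11 (-12.24 ± 0.35), srlf-17 (-11.87 ± 0.17), clec-137 (-11.37 ± 0.84), clec-94 (-11.30 ± 0.34) and clec-138 (-11.13 ± 0.58). Adjusted p lay between 5.76e-13 and 1.50e-06. The fixed genes vit-2 (6.61 ± 0.28), rme-2 (5.22 ± 0.21), spe-9 (-2.12 ± 0.41) and lov-1 (-3.66 ± 0.95) had adjusted p from 6.75e-10 to 0.0042. At the 40th percentile pseudocount nlp-39, sdz-25, ztf-25, sea-1 and folt-3 were at 4.99, 4.18, 3.86, 3.79 and 4.15, srlf-18, srlf-11, srlf-17 and clec-138 at -7.80, -6.58, -7.16 and -6.72, spe-9 at -0.98 and lov-1 at -1.86. With the one at the 20th sdz-25 and sea-1 were at 5.67 and 5.14.

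In fasted worms 18 lists passed the test, 5 higher and 13 lower in hermaphrodites, and the median difference of all genes was -0.18 (0.07, 0.06 and -0.01 under median centring, quantile normalization and hybridization control scaling). All 23 oogenesis genes, all 29 DNA replication genes and all 5 vitellogenin genes were higher, also over the list alone (medians relative to all genes 4.76, 2.92 and 6.51; camera adjusted p = 8.39e-16, 1.12e-14 and 3.36e-04). Of 31 proteasome genes 25 were higher (25, relative 0.74, 1.15e-05), and of 199 SCF genes 98 were higher and 49 lower (98 and 50, relative 1.01, 0.0039). Lower in hermaphrodites were 49 of 50 sperm genes (49, relative -6.31, 6.11e-11), all 12 male somatic genes (12, relative -4.47, 2.79e-04), 109 of 137 C-type lectins (109, relative -2.07, 6.08e-10), 40 of 53 UDP-glucuronosyltransferases (40, relative -1.16, 7.65e-05) and 17 of 19 neuron markers (17, relative -1.39, 1.99e-04). So were 12 of 18 muscle markers (12, relative -0.75, 0.0055), 89 of 152 nuclear hormone receptors (89, relative -0.65, 0.0055), 12 of 16 intestinal proteases (12, relative -1.12, 0.0091), 14 of 20 insulin-like peptides (14, relative -1.28, 0.0163), 7 of 8 glyoxylate cycle genes (7, relative -0.86, 0.0279), 8 of 13 pharynx markers (8, relative -1.15, 0.0344) and 10 of 14 intestine markers (10, relative -0.64, 0.0414). Of 61 ribosomal protein genes 24 were lower and 1 higher (12 and 1, median -0.28, relative -0.11, 0.0194), with a median of 0.06 after quantile normalization (0.385).

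With an estimated correlation 4 of these 18 lists in fasted worms kept their call, at adjusted p of 0.0038 for oogenesis, 0.0036 for DNA replication and for lectins, and 0.0184 for neurons. It was 0.0847 for male somatic genes to 0.697 for ribosomal proteins in the other 14. Calls also ended with the stricter filter for SCF genes (0.110), after quantile normalization for receptors (0.101) and pharynx (0.0783), and after median centring for the glyoxylate cycle (0.054). That of ribosomal proteins ended after median centring (0.517), quantile normalization (0.385) and on hybridization controls (0.326), and that of intestine in 7 other settings (0.0518 to 0.0753). Leaving out 1 array ended the calls of ribosomal proteins (0.0693 and 0.0572 without hermaphrodite fasted replicates 1 and 3, 0.0608 without male fasted replicate 2), pharynx (0.0572 without hermaphrodite fasted replicate 3) and intestine (0.062 and 0.0512 without hermaphrodite fasted replicates 2 and 3, 0.0537 and 0.0522 without male fasted replicates 1 and 3). The other 17 lists had adjusted p from 0.0865 for cytochrome P450 and for trehalose genes (the latter 0.0354 with no filter, 0.0409 after quantile normalization) to 0.967 for heat shock genes, whose median and mean differed in sign.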

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

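The tests of mixed worms, the readings over 3 scalings and that of the sperm list by 1 array were chosen after seeing the result, while the scalings and left-out arrays were planned, as was median centring for the rises.

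Of 75 named limma interaction calls (hermaphrodite minus male change, log2) 36 held in every alternative. Fasting responses differed by sex for these genes and lists. Among those with a higher change in hermaphrodites, adjusted p in parentheses, were asm-3 at 5.46 (0.0194), clc-11 at 5.29 (0.0215), clec-61 at 4.91 (0.0050), clec-183 at 4.49 (0.0129), clec-64 at 4.07 (0.0250), col-129 at 4.05 (0.0438), hsd-2 at 3.75 (0.0011) and irg-5 at 3.37 (6.44e-04). Next came clx-1 at 3.25 (0.0198), cpt-6 at 3.25 (0.0017), irg-4 at 3.25 (0.0155), nhr-125 at 2.99 (0.0138), hsp-12.3 at 2.72 (0.0018), asp-14 at 2.19 (0.0215), adh-1 at 2.13 (0.0035), ugt-36 at 1.85 (0.0419) and asp-13 at 1.77 (0.0467). The smaller ones were drd-50 at 1.69 (0.0376), sod-3 at 1.51 (0.0320), perm-2 at 1.43 (0.0020), gst-24 at 1.40 (0.0012), myo-3 at 1.39 (0.0055), vha-19 at 0.92 (0.0149), ech-6 at 0.81 (0.0110) and vha-15 at 0.68 (0.0376).

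Genes with a lower change in hermaphrodites were cpr-4 at -3.48 (0.0019), cyp-13A5 at -3.39 (0.0456), cpr-5 at -3.22 (0.0062), ins-35 at -3.07 (0.0084), lipl-1 at -3.07 (0.0189), lips-11 at -2.99 (0.0044), cnc-6 at -2.95 (0.0295), dscc-1 at -2.93 (0.0388) and tag-164 at -2.58 (0.0374). To these add clec-54 at -2.57 (7.76e-04), rcd-1 at -2.51 (7.76e-04), col-183 at -2.35 (0.0375), ugt-18 at -2.31 (0.0029), ins-7 at -2.28 (0.0101), asp-1 at -2.05 (8.48e-04), acs-11 at -1.96 (0.0497), srap-1 at -1.71 (0.0493), zig-3 at -1.61 (0.0423) and cpr-1 at -1.56 (0.0236). The smaller ones were mex-6 at -1.25 (0.0093), spe-44 at -1.03 (0.0154), rnr-1 at -0.94 (0.0346), mcm-6 at -0.87 (0.0124), rpt-1 at -0.74 (0.0356), rpn-9 at -0.70 (0.0420) and epg-6 at -0.62 (0.0421).

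By list median, with the camera adjusted p, the differences were 0.55 for body wall muscle (1.37e-06), 0.49 for insulin-like peptides (0.01), 0.42 for glutathione S-transferases (3.07e-04), 0.34 for the vacuolar ATPase (7.40e-05), 0.33 for cuticle collagens (6.20e-04), 0.32 for fatty acid oxidation (3.07e-04) and 0.24 for UDP-glucuronosyltransferases (0.0069). The lower ones were -0.99 for sperm (0.0322), -0.65 for oogenesis (1.13e-04), -0.41 for DNA replication (2.51e-04) and -0.36 for the proteasome (4.20e-05). With an estimated correlation adjusted p was 0.0364 for the vacuolar ATPase and fatty acid oxidation, and the other 9 of 11 calls ended, at 0.0925 for DNA replication to 0.697 for sperm. The sperm median was -0.08 (0.944) without hermaphrodite fed replicate 1 and the collagen median 0.04 (0.116) without male fasted replicate 3.

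In fasted males 17 of 29 DNA replication genes rose (adjusted p = 0.0256 with an estimated correlation), and 9 of 23 oogenesis genes rose and 2 fell, a list call that ended with an estimated correlation (adjusted p = 0.249) and in 4 other settings (0.0544 to 0.109). Hermaphrodites among the fasted males would have to supply a median of 1.48% of the RNA for the risen oogenesis genes and 7.18% for the risen DNA replication genes, while the share is capped at 1.28% by vit-2, 1.70% by vit-4, 1.95% by vit-5 and 9.77% by vit-6. More than each cap is needed by 16, 13, 12 and 3 of 17 DNA replication genes, so the lowest cap, which any share has to meet, excludes mixing as the whole cause there, and by 6, 3, 3 and 0 of 9 oogenesis genes, where it stays open. Median centring and hybridization controls shift whole arrays, so list medians above all genes cannot move. After quantile normalization they were 0.165 for oogenesis (call lost) and 0.2188 for DNA replication (call kept in each scaling). The latter is within the SD of the members (0.2391), which is no test of it, so scaling stays open for both lists. In an earlier form of this test 6 of 9 and 7 of 17 risen genes stayed called after median centring. A change in the males themselves was not tested apart from these.

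More probe sets rose than fell in fasted males, 69.6% of the calls. After median centring, which moves the split toward balance by its construction, rises were 41.9%, after quantile normalization 56.7% and on hybridization controls 73.3%. The scalings do not give the same answer, so the scaling of the arrays stays open as the cause. Whether total RNA changed cannot be read from arrays scaled to the same mean, and no biological explanation was tested.

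The sperm list was lower in fasted hermaphrodites by camera (adjusted p = 1.60e-04), but not with an estimated correlation (0.458) or by fry (0.232), and 2 of 50 genes fell, none over the list alone. The camera call needs fed replicate 1 (0.326 without). Sperm medians fell in each pair, from 9.16, 6.64 and 6.72 fed to 7.77, 6.32 and 5.83 fasted. Males in fed replicate 1 were tested by the level their RNA would give 6 male somatic markers, and 1 of 6 reached it. Of 3 forms 1 was for, 1 against and 1 open. The allowed share rose by taking cwp-1 (0.59) and cwp-2 (0.98) as 6.01, so this stays open.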

How the results depend on the processing

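In each single setting most named gene calls kept their side of the threshold and none reversed, while most list calls were lost with an estimated correlation. Of 601 named calls, 589 and 591 were kept with the pseudocounts at the 40th and 20th percentiles (the latter chosen after seeing the data), 578 with no filter, 562 after quantile normalization, 561 after median centring, 555 on hybridization controls, 555 without the trend, 595 with array weights, 601 with the replicate block, and 539 to 575 with 1 array left out. The stricter filter kept 544 of the 545 still tested, and only the arrays compared kept 498 of 526. For fasting, calls kept in every alternative were 68 of 102 in hermaphrodites, 103 of 127 in males and 36 of 75 for the difference. Leaving the pseudocount out is the fit itself, since the values were deposited on the log2 scale, and was not run as an alternative. The fit with only the arrays compared cannot give the difference. Calls of the difference of the fasting response numbered 354 on hybridization controls, 1522 with array weights and 1641 with the replicate block against 840, and the cause was not tested. At 2-fold or more there were 999 calls in hermaphrodites, 1495 in males, 500 for the difference and 565 shared, since this asks more of each call. Leaving out 1 array gave 1353 to 1860 calls in hermaphrodites, 3339 to 4383 in males, 428 to 899 for the difference, 11274 to 12000 and 10570 to 11367 for sex in fed and fasted worms, and 868 to 1045 shared, with fewer samples in each. With an estimated correlation 14 of 59 process list calls and 7 of 25 marker list calls were kept, and with fry 54 and 22. By fry, which tests against no change, the SCF list (median 0.20) and neurons (median 0.12) went up in males, adjusted p = 0.0175 and 0.0453, while camera, which tests against the other genes (median 0.237), called neither (0.612 and 0.869). Ribosomal medians turned positive after quantile normalization, for reasons not tested. This held for fasting in hermaphrodites and in males (0.0778), and between the fed (0.1008) and fasted (0.0601) sexes. Signal near the lower end of the scale limits the size of changes, which shrink with a pseudocount.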

Other observations

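Of the tests in this part, the sorting of the draws by direction and the splits that keep the pairs were chosen after seeing the result.

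Other splits of the arrays were run for each count of calls. In each comparison of 3 against 3 arrays, 1 of 10 splits, the real one, had as many called probe sets. The highest other counts were 5 for fasting in hermaphrodites, 2 for fasting in males, and 0 for each sex comparison, and 10 splits are too few for a share under 0.05. For the difference of the fasting response, 7 of 100 draws, which do not keep the pairs of same-numbered arrays, had as many calls as the 840 found, with up to 4596 in another draw, so a chance split of the arrays is not excluded by this test. Of those 7 draws, 6 turn the direction of fasting in 1 sex, which moves the fasting response itself into the difference. Among the 48 draws that keep the direction, 1 had as many calls, and the highest other count was 778. For shared calls in the same direction, 1 of 100 draws, the real one, reached 1083, and the highest other was 32. Most splits leave few calls per sex, so overlap is not tested.

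With the replicate block, fed and fasted were also exchanged within same-numbered pairs, which gives 32 splits. For the difference, 2 of 32 had as many calls as the 1641 found, so a chance split is not excluded by this test either. The other of the 2, with 5536, exchanges all 3 male pairs, which adds the fasting responses of the sexes instead of subtracting them, a structure of the samples. Among the 16 splits that keep the direction, 1 had as many, and the highest other count was 279. For shared calls, 1 of 32 splits, the real one, reached 1470. The highest other, 74, exchanges all 3 male pairs. Overlap is again not tested.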
